A study of Mus musculus with 7 samples.

How the data were processed

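Intestinal epithelial cells were isolated from the proximal intestine of male mice aged 8 weeks with 2 mM EDTA, and total RNA was extracted with a phenol reagent, per the labels and the series' design text. The mice had been backcrossed for more than 6 generations to C57BL/6J, and tamoxifen was injected at 80 mg/kg per day on 2 days, per the labels' protocols. The groups were control (2 arrays), knockout at day 4 (2), day 7 (2) and day 10 (1). The design text names times of 0, 4 and 7 days with 2 different mice at each, while the labels describe the controls as floxed mice taken 7 days after tamoxifen and give a sample at day 10, so the control was treated as a group without deletion whose day is not settled. All arrays carried 1 colour (Cy3) and lay on 1 slide scanned in 1 session, so that no batch of slide or scan could be tested.

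The intensity values were deposited as scanner output of Agilent Feature Extraction 11.5.1.1 for array design 028005, per the file headers, in which gProcessedSignal is the spot signal after background subtraction and spatial detrending, with no scaling between arrays. The file headers give mm9 as the genome build label. The deposited value table of the series equalled gProcessedSignal within 0.1% for 100% of probes with a single spot on each array, with column medians from 15.2 to 30.5, so that it was linear and not centred. How it combined probes with several spots stays unknown, since between 66.0% and 90.7% of these lay within 1% of the mean of their spots. It was used as an alternative.

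Control spots were left out. The other 59305 spots held 55681 probes. Spots marked as outliers by the scanner software (115 to 274 per array) were also left out, and the remaining spots of a probe were averaged on the log2 scale. Accessions in the files were named through a RefSeq table of assembly GRCm38.p6, through which 27509 probes had 1 gene symbol, none had several and 28172 had none. These made 20887 genes. No coordinates are given because that assembly differs from the build label in the files. The value of a probe was log2(gProcessedSignal) minus the array's 75th percentile. Less than 50% of the probes were well above background on 6 of the 7 arrays. Scaling to the probes detected on all arrays can be preferable there, and it was added as an alternative after the data were seen, while the scaling over all probes, fixed earlier, was kept as the main setting. Probes not well above background on at least 2 of 7 arrays were left out, a gene was represented by its brightest probe over all arrays, and probes without a symbol stayed as features of their own. This gave 24760 features, of which 13802 had a symbol and 10958 did not, after 46 probes were left out for a spot marked as an outlier. Where a gene was not well above background on any array of a group, its fold is a lower bound, written as "at least", against the lowest signal well above background on those arrays or the gene's own signal if higher (between -4.72 and -4.13 on the scaled log2 axis). These bounds hold for the main setting only, since the offset added with normexp lowers the differences of dim probes by construction.

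limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) fitted 1 mean per group over all 7 arrays, with lmFit and eBayes, 2-sided tests and Benjamini-Hochberg adjustment over all features, called at an adjusted p under 0.05. The fit had 3 residual and 3.16 prior degrees of freedom. The replicates of a group were different mice per the design text. The lone day 10 array was assumed to vary like the other groups. Correlations between the arrays of a group over features were 0.986 for control, 0.988 for day 4 and 0.977 for day 7, and no pair of arrays was a duplicate.

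The groups, the tests, 35 gene lists, the rule for named genes and all alternatives except the added scaling were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists with at least 5 measured genes. The erythroid list had fewer and was not tested. Several lists as fixed share members, so their shifts are not independent. For example, Zg16 is in the goblet cell and pancreas lists, and Areg and Ereg are in the YAP and TAZ target and fetal-like lists. Cck and Gip are in the enteroendocrine and proximal intestine lists, and Cyp3a11 is in the enterocyte and xenobiotic lists. With an estimated correlation no list was called in any comparison, with lowest adjusted p of 0.45 at day 4, 0.27 at day 7, 0.26 for day 7 minus day 4 and 0.16 at day 10. The named genes were Mob1a and Mob1b, the 8 highest and 8 lowest differences at day 4 and day 7 (5 and 5 for the other comparisons), and up to 4 members with the smallest p of each study list and up to 2 of each other list. The highest and lowest were taken among genes with a symbol, an adjusted p under 0.05, all arrays of 1 group above all of the other and a signal well above background on all arrays of at least 1 group. If fewer passed, those that passed were taken, and if none passed, the 5 smallest p each way, reported as not passing. A selection of these is printed, and 2 genes that the rule names are not reported here. A gene that 2 parts of the rule name counts under both, and genes outside the rule are said to have been chosen after their values were seen. Overlap of calls was compared with 50 simulations of unchanged groups against the shared controls.

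The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes or only probes well above background on all 7 arrays, outlier marks ignored, the mean of a gene's probes, an intensity trend in eBayes, only the 2 groups compared, no day 10 array, a replicate block, a fold of at least 2, the deposited value table, and leaving out each replicate of control, day 4 and day 7. Normexp used gMedianSignal in place of the planned gMeanSignal, which was not used here.

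The fit was tested on simulated data with 24760 features and 200 changed genes in each of 20 runs. For day 7 minus control it recovered 3.3% of 2-fold, 78.4% of 4-fold, 96.2% of 8-fold and 98.6% of 16-fold changes with 11.75 unchanged genes called per run. For day 7 minus day 4 it recovered 2.9%, 78.0%, 95.6% and 98.4%, and for day 10 minus control 0.4%, 43.9%, 89.6% and 96.5%. In simulations of day 4 with no change, 0.1 genes were called per run. A list shifted by 1 on the log2 scale at day 7 was called in 20 of 20 runs with the preset correlation and in 0 of 20 with an estimated correlation, and no list without a shift was called. Noise was drawn independently for each gene. These runs therefore do not test how the preset correlation behaves when members of a list vary together. Far fewer genes were changed in them than the 1847 and 6953 features called in the data at day 7 and day 10. The shares recovered can therefore differ from those in the data.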

Results

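Gene expression was measured in intestinal epithelial cells of mice after inducible deletion of Mob1a and Mob1b, adaptor proteins that activate the Lats kinases of the Hippo pathway. Floxed alleles of both genes were recombined by tamoxifen through CreERT2, a Cre recombinase fused to a ligand-binding domain of the oestrogen receptor, driven in the intestinal epithelium by the Villin promoter. Each sample was hybridised to a 1-colour array, with 2 arrays of control mice without Cre, 2 arrays of knockout mice at day 4 after tamoxifen, 2 at day 7 and 1 at day 10. All 7 arrays lay on 1 slide and were scanned in 1 session. The control and day 4 arrays lay in row 1 of that slide and the day 7 and day 10 arrays in row 2, so that slide row cannot be told apart from the difference of day 7 or day 10 from control, or from the step from day 4 to day 7. Between 45.2% and 51.3% of probes were well above background on an array, and no spot was saturated. The 75th percentile of the signal was between 315 and 395 on the control, day 4 and day 7 arrays and 545 on the day 10 array. The small number of arrays limits the precision of every value. Levels are log2 signals relative to the array's 75th percentile, and differences are given on the log2 scale with their standard error (SE) from limma.

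Mob1b, the targeted gene with 2 informative probes, was lower in every knockout array than in both controls. Its brighter probe had a level of -1.02 ± 0.16 (SD, n = 2) in controls, -2.44 ± 0.04 at day 4 (SD, n = 2), -2.60 ± 0.17 at day 7 (SD, n = 2) and -2.65 on the day 10 array. The difference from control was -1.43 ± 0.22 at day 4 (adjusted p = 0.19), -1.59 ± 0.22 at day 7 (adjusted p = 0.014) and -1.64 ± 0.27 at day 10 (adjusted p = 0.0070). The other Mob1b probe differed from control by -1.0 at day 4 and -1.66 at day 7. Mob1a had 1 probe, which was dim and well above background on 5 of 7 arrays. Its level differed from control by -0.27 ± 0.25 at day 4 (adjusted p = 0.94) and 0.25 ± 0.25 at day 7 (adjusted p = 0.59), and rose by 1.60 ± 0.30 on the day 10 array (adjusted p = 0.011). The Mob1a call at day 10 ended with normexp background correction (adjusted p = 0.14, the highest of its alternatives, which went down to 0.0088). The Mob1b call at day 7 ended without control replicate 1 (adjusted p = 0.086) and without day 7 replicate 1 (0.056). Whether the Mob1a and Mob1b probes lie inside the deleted exons was not known, so the probes do not by themselves check the knockout labels.

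**Figure D1:**
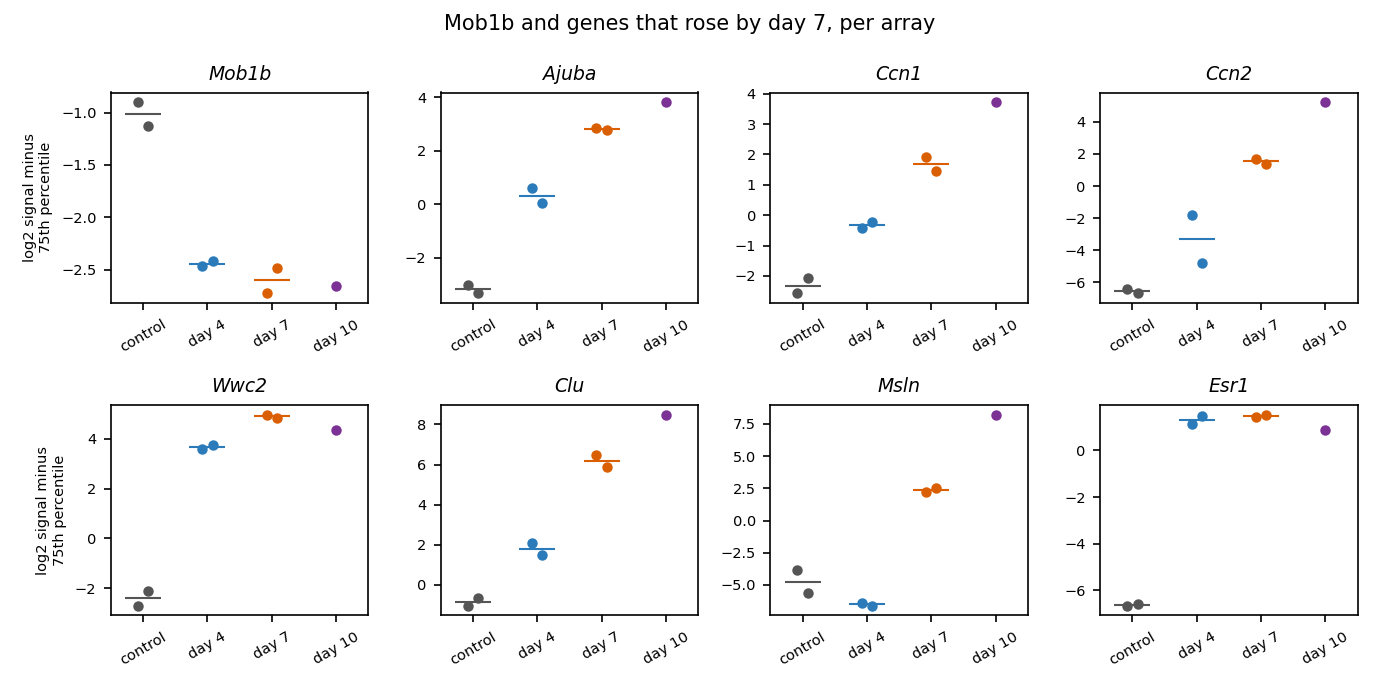
Log2 signal minus the array's 75th percentile (y axis) for Mob1b and 7 genes that were higher at day 7, by group (x axis), with 1 point per array and a line at the mean of each group of 2. Mob1b fell from -1.02 in controls to -2.60 at day 7, while Ajuba went from -3.18 to 2.80 and Clu from -0.84 to 6.17.

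The comparison at day 4 asked which transcripts differ first from control after tamoxifen. The controls lack Cre, so effects of CreERT2 activity cannot be told apart from those of the deletion in any difference from control. Wwc2, a relative of the Hippo activator Kibra, was 67.3-fold higher than in controls (6.07 ± 0.27, adjusted p = 0.0046), and Ajuba, a scaffold that restrains the Lats kinases, was 11.3-fold higher (3.50 ± 0.28, adjusted p = 0.043). Esr1, the oestrogen receptor gene whose ligand-binding part is used in CreERT2, was at least 59.6-fold higher by 1 of its 3 probes, while the other 2 probes were not well above background on any array. The other genes that rose were Tdrp (at least 10.6-fold), the glycosyltransferase gene Mgat4c (14.4-fold, well above background on 1 of 2 control arrays), Sh3tc2 (at least 3.23-fold), the phospholipase gene Pla1a (10.0-fold) and Ccdc154 (at least 2.72-fold), with adjusted p between 0.028 and 0.043. These 8 genes were all the calls among 24760 features tested by limma. No feature was called lower, while 1542 had an unadjusted p under 0.05.

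As a group, 18 measured target genes of the transcription coactivators YAP and TAZ, which Hippo signalling restrains, shifted upwards at day 4 with a median difference of 0.35 (camera, adjusted p = 4.23e-06; adjusted p = 0.66 with an estimated correlation). Only Ajuba among them was called over all genes, and 5 members passed when adjusted over the list alone. The median was 0.87 without day 4 replicate 1, 0.10 without day 4 replicate 2, 0.67 without control replicate 2, 0.12 with no filter on dim probes and 0.72 with only probes well above background on all 7 arrays. The secreted matrix protein gene Ccn1 differed by 2.01 ± 0.28 (adjusted p = 0.15) and the angiomotin family gene Amotl2 by 1.34 ± 0.23 (adjusted p = 0.25). The list of 20 Hippo pathway components, which includes Wwc2, also shifted upwards (median 0.10, adjusted p = 0.030; adjusted p = 0.66 with an estimated correlation), with 2 higher and 1 lower when adjusted over the list alone. This call ended without control replicate 2 (adjusted p = 0.21), without day 4 replicate 1 (0.066), with quantile normalization (0.058) and with normexp background correction (0.087), within a range from 0.0067 to 0.21 over its alternatives. With normexp the median was -0.08, while camera gave an upward direction. The targeted genes Mob1a and Mob1b are also members of this list.

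Interferon-stimulated genes shifted upwards together (24 members, median 0.60, adjusted p = 6.70e-12; adjusted p = 0.45 with an estimated correlation). None of them was called over all genes and 7 passed when adjusted over the list alone. Examples were Ifi44 (1.37 ± 0.28, adjusted p = 0.34) and Oas1g, which was at least 1.51-fold higher (adjusted p = 0.33), both genes of the antiviral response. With members that were not well above background in 1 group at their bounds, the median of the list was 0.59. Goblet cell genes shifted downwards (16 members, median -0.61, adjusted p = 2.08e-05; adjusted p = 0.71 with an estimated correlation), with none called over all genes and 6 lower when adjusted over the list alone. Klk1, a tissue kallikrein, differed by -1.19 ± 0.29 and Creb3l1, a transcription factor of secretory cells, by -0.95 ± 0.23. Enteroendocrine genes also shifted downwards (22 members, median -0.26, adjusted p = 0.026; adjusted p = 0.75 with an estimated correlation), with Neurog3 at -1.02 ± 0.23 and no member called over all genes or when adjusted over the list alone. That call ended without either control replicate (adjusted p = 0.071 and 0.078), without either day 4 replicate (0.066 and 0.062), with normexp background correction (0.067) and with no filter on dim probes (0.11), the highest of its alternatives, which went down to 0.0062. Immediate early and heat shock genes shifted downwards (19 members, median -0.36, adjusted p = 0.0035; adjusted p = 0.71 with an estimated correlation), with Fosb at -2.94 ± 0.31 and Dusp1 at -1.58 ± 0.28. None of them was called over all genes and 3 were lower when adjusted over the list alone. The call of this list ended without control replicate 2 (median -0.35) and without day 4 replicate 1 (median -0.16). Proliferation genes shifted upwards (30 members, median 0.22, adjusted p = 0.0031; adjusted p = 0.75 with an estimated correlation), with no member called over all genes or when adjusted over the list alone. Without day 4 replicate 1 the median of the proliferation genes was -0.18 (adjusted p = 0.22), and without control replicate 2 their adjusted p was 0.21.

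The target genes of the Wnt pathway, which maintains intestinal stem cells, did not pass the test at day 4 (18 members, median -0.02, adjusted p = 0.69), nor did the stem cell genes (20 members, median -0.11, adjusted p = 0.99) or the genes of the BMP and TGF-beta pathways (24 members, median -0.02, adjusted p = 0.36). In these 3 lists camera gave an upward direction while the median was below 0. Among their members, the Wnt antagonist gene Notum differed by -1.44 ± 0.36 (adjusted p = 0.46), the stem cell transcription factor gene Ascl2 by -0.77 ± 0.28 (adjusted p = 0.73) and the TGF-beta receptor gene Tgfbr2 by 0.86 ± 0.22 (adjusted p = 0.46). Clu, a marker of regenerating epithelium, differed by 2.62 ± 0.34 (adjusted p = 0.12) and Il33, an alarmin, by 1.99 ± 0.28 (adjusted p = 0.15). The defensin gene Defa21 of Paneth cells differed by -1.34 ± 0.20 (adjusted p = 0.18). Markers of other cell types did not pass at day 4. B cell and plasma cell markers had a median of -0.71 (11 members, -0.49 with dim members at their bounds, adjusted p = 0.070) with none called over all genes or when adjusted over the list alone. They passed without control replicate 1 (adjusted p = 1.22e-04), without either day 7 replicate or with only the 2 groups compared (0.041) and with the replicate block (0.034). They also passed with normexp background correction (0.0093), median scaling (0.030) and only probes well above background on all 7 arrays (0.043), within a range from 1.22e-04 to 0.71 over their alternatives. The adjusted p was 0.36 for T cell, 0.89 for myeloid, 0.40 for fibroblast, 0.58 for smooth muscle, 0.79 for endothelial, 0.18 for pancreas and 0.36 for enteric neuron and glia markers.

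The count of 8 calls at day 4 fell to 3 without control replicate 1 or either day 7 replicate and to 1 without either day 4 replicate, and it was 8 without control replicate 2, of which 3 were higher and 5 lower, with 2 genes in common. Esr1 was the 1 gene called without each replicate in turn, and median scaling gave 27 calls, of which 88.9% were higher. With normexp background correction the calls of Sh3tc2 (0.58, adjusted p = 0.80), Ccdc154 (0.42, adjusted p = 0.80) and Tdrp (1.43, adjusted p = 0.19) ended, at sizes below the bounds given. Over all alternatives their adjusted p was 0.0075 to 0.80, 0.030 to 0.80 and 0.0076 to 0.51. The calls of all but Esr1 and Wwc2 ended with no filter on dim probes (adjusted p between 0.12 and 0.15), only the 2 groups compared (0.085 to 0.11) and the replicate block (0.067 to 0.084). Scaling to the probes detected on all arrays ended those of Tdrp, Ajuba, Pla1a and Ccdc154 (0.061), quantile normalization those of Pla1a (0.058) and Ccdc154 (0.063), and the mean of a gene's probes that of Tdrp (0.069).

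At day 7 Efemp1, which encodes the matrix protein fibulin-3, was at least 238-fold higher than in controls (adjusted p = 0.0035). Ccn2, a secreted matrix protein and YAP target, was at least 70.7-fold higher (adjusted p = 0.0066), and Cst9, a cystatin gene, at least 95.2-fold higher (adjusted p = 0.0035). The surface glycoprotein gene Msln was 138-fold higher and the predicted gene Gm10046 was 311-fold higher, each well above background on 1 of 2 control arrays. Wwc2 was 157-fold higher, Sh3tc2 at least 58.1-fold higher and the Esr1 probe at least 67.8-fold higher. The deepest fall was in Slc16a9, a monocarboxylate transporter family gene, which was at least 362-fold lower by its brighter probe. The cytochrome gene Cyp2c55 was 117-fold lower, the carboxylesterase genes Ces1f 57.0-fold and Ces1d 54.7-fold, the cytochrome gene Cyp3a57 48.0-fold and the proton channel gene Otop3 62.4-fold lower. Cyp2c55 and Ces1d were well above background on 1 of 2 day 7 arrays. The kallikrein gene Klk1b4 was 47.0-fold lower and Klk1b26 was 45.6-fold lower by 1 of its probes, the other being not well above background on any array. The Klk1b, Cyp2c, Cyp3a, Ces1 and defensin genes have close relatives, and which member a probe measured is uncertain.

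In all, 1847 of 24760 features were called at day 7, of which 732 were higher and 1115 lower. Of these, 1292 had a gene symbol (523 higher, 769 lower). The excess of lower calls was not seen without control replicate 1 (267 higher, 255 lower) or without day 7 replicate 1 (417 higher, 390 lower).

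Of the 18 YAP and TAZ target genes, 9 rose at day 7 and none fell (median 1.71, camera adjusted p = 1.87e-10; adjusted p = 0.27 with an estimated correlation), and 11 were higher when adjusted over the list alone. The median was 1.56 with dim members at their bounds, 0.90 with normexp background correction and 1.03 with no filter on dim probes. Ajuba rose 63.0-fold (5.98 ± 0.28, adjusted p = 0.0013), Ccn1 16.2-fold (4.02 ± 0.28) and Amotl2 5.48-fold (2.45 ± 0.23). Among the 20 Hippo pathway components 5 rose and 2 fell (median 0.36, adjusted p = 0.012; adjusted p = 0.27 with an estimated correlation), with 7 higher and 2 lower when adjusted over the list alone. This call ended with no filter on dim probes (adjusted p = 0.079, where its other alternatives went down to 0.0090). Mob1b, a targeted gene, was among the members of the Hippo list that fell. Tead1, a DNA-binding partner of YAP, rose by 2.56 ± 0.27 by its brightest probe, while the other probe well above background on all 7 arrays differed by 0.39.

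Wnt target genes shifted downwards at day 7. Of 18 members 5 fell and none rose (median -0.63, adjusted p = 0.035; adjusted p = 0.35 with an estimated correlation), and when adjusted over the list alone 9 were lower and 1 was higher. Ascl2 fell by 2.75 ± 0.28 (adjusted p = 0.0056), Sp5, a direct Wnt target, by 1.71 ± 0.33 (adjusted p = 0.034) and Lgr5, the receptor gene that marks crypt base stem cells, by 1.56 ± 0.29 (adjusted p = 0.030). Of 20 stem cell genes 5 fell and none rose (median -0.57, adjusted p = 0.0013; adjusted p = 0.31 with an estimated correlation), and 9 were lower and 1 higher when adjusted over the list alone. Rnf43, a membrane regulator of Wnt receptors, fell by 1.59 ± 0.32 (adjusted p = 0.039). The Wnt target and stem cell lists share Lgr5, Ascl2, Axin2, Rnf43, Znrf3 and Tnfrsf19, so their shifts are not independent in any comparison. The calls of Lgr5, Sp5 and Rnf43 ended without control replicate 1 (adjusted p = 0.14, 0.15 and 0.15), without control replicate 2 (0.091, 0.10 and 0.12) and without day 7 replicate 1 (0.10, 0.14 and 0.11), those of Lgr5 and Rnf43 without either day 4 replicate (0.064 and 0.082), and that of Sp5 without day 7 replicate 2 (0.066). The call of Rnf43 also ended with quantile normalization (0.052) and with scaling to the probes detected on all arrays (0.057). The Wnt call ended without control replicate 2 (adjusted p = 0.064), without either day 4 replicate or with only the 2 groups compared (0.052) and without day 7 replicate 2 (0.22). It also ended with normexp background correction (0.051) and the mean of a gene's probes (0.052), and its adjusted p was between 0.0012 and 0.22 over the alternatives with the preset correlation.

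Genes of the BMP and TGF-beta pathways shifted upwards at day 7, with 3 of 24 members higher and 1 lower (median 0.26, adjusted p = 0.017; adjusted p = 0.35 with an estimated correlation). With p adjusted over the list alone, 6 were higher and 3 lower. The ligand genes Bmp8b and Bmp2 rose by 2.72 ± 0.28 (adjusted p = 0.0056) and 2.33 ± 0.33 (adjusted p = 0.014), and Tgfbr2 rose by 2.06 ± 0.22 (adjusted p = 0.0064). The call of the list ended without control replicate 2 (median 0.13) and without day 7 replicate 1 (median 0.31). It also ended with no filter on dim probes (camera adjusted p = 0.41), the highest of its alternatives, which went down to 4.61e-04. The call of Bmp2 ended without control replicate 1 (adjusted p = 0.066) and without control replicate 2 (0.058).

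Secretory cell genes fell at day 7. Of 16 goblet cell genes 12 fell and none rose (median -2.44, adjusted p = 4.54e-13; adjusted p = 0.28 with an estimated correlation), and 15 were lower when adjusted over the list alone. Klk1 was 41.3-fold lower (-5.37 ± 0.29, adjusted p = 0.0013) and Agr2, a chaperone of mucin folding, 8.64-fold lower (-3.11 ± 0.21, adjusted p = 0.0022). Of 22 enteroendocrine genes 7 fell (median -1.05, adjusted p = 1.09e-08; adjusted p = 0.31 with an estimated correlation), and 14 were lower when adjusted over the list alone. Neurog3, the transcription factor of endocrine progenitors, was 13.9-fold lower (-3.80 ± 0.23) and the neuropeptide gene Tac1 4.22-fold lower (-2.08 ± 0.28). Of 10 Paneth cell genes 4 fell (median -1.11, adjusted p = 4.83e-06; adjusted p = 0.27 with an estimated correlation), and 8 were lower when adjusted over the list alone, with Defa21 at -3.18 ± 0.20 and Habp2 at -2.37 ± 0.35. Tuft cell genes shifted downwards (15 members, median -0.91, adjusted p = 0.0075; adjusted p = 0.57 with an estimated correlation), with 1 called on each side and 1 higher and 8 lower when adjusted over the list alone. Ltc4s, a leukotriene synthase gene, fell by 2.69 ± 0.26 and Ptgs1, which encodes cyclooxygenase 1, rose by 2.16 ± 0.30. The tuft cell call ended without day 7 replicate 1 (median -0.57). The 30 genes of enterocyte digestion and absorption did not pass as a list (median -0.30, adjusted p = 0.14), although 4 fell, among them the retinol-binding protein gene Rbp2 (-1.45 ± 0.24) and the glucose transporter gene Slc2a2 (-1.61 ± 0.29). That list passed without control replicate 1 (adjusted p = 0.022), without day 7 replicate 2 (0.017) and with no filter on dim probes (0.0031), within a range up to 0.79 over its alternatives.

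**Figure D2:**
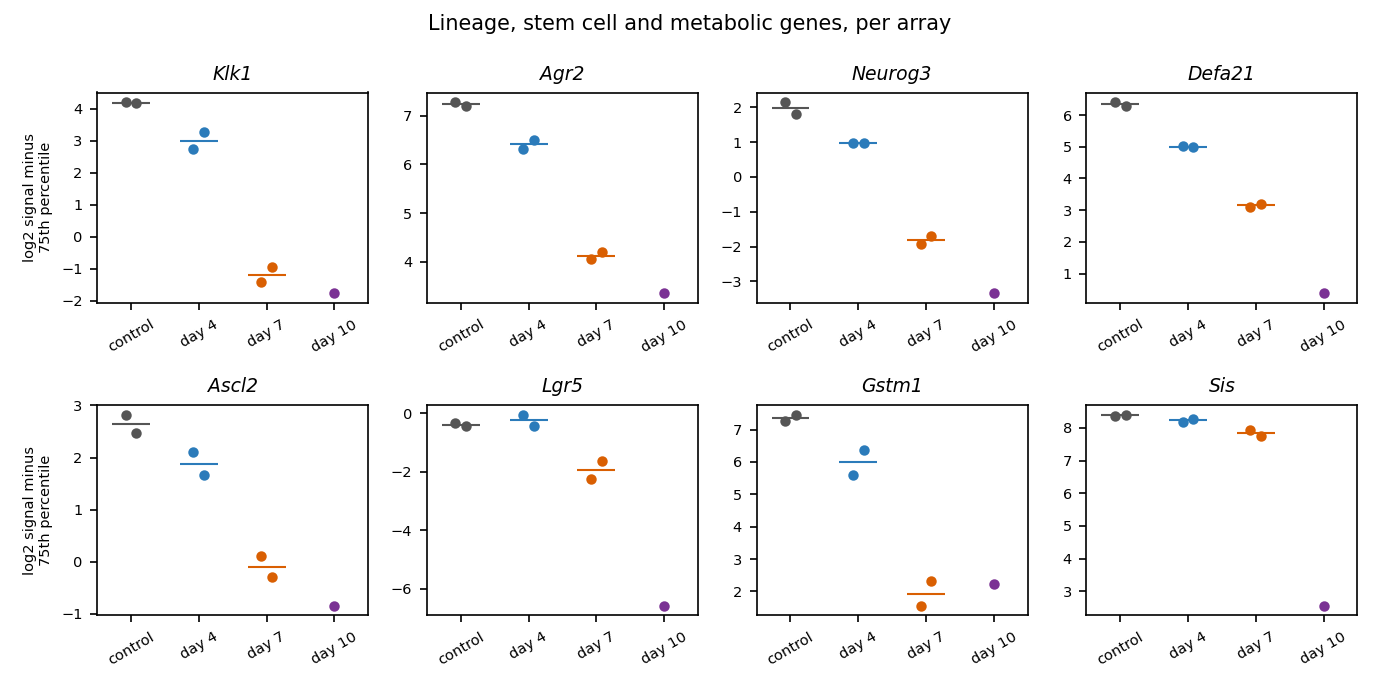
Log2 signal minus the array's 75th percentile (y axis) for lineage, stem cell and metabolic genes by group (x axis), with 1 point per array and a line at the mean of each group of 2. Klk1 averaged 4.19 in controls, 3.00 at day 4 and -1.18 at day 7, while Sis was 8.40 in controls, 7.85 at day 7 and 2.55 on the day 10 array.

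Fetal-like and regenerative epithelial genes had the smallest p among the lists that shifted upwards at day 7, with 13 of 20 members higher and none lower (median 2.31, adjusted p = 1.68e-14; adjusted p = 0.27 with an estimated correlation). With p adjusted over the list alone, 17 were higher and 1 was lower. Clu rose 129-fold (7.01 ± 0.34, adjusted p = 0.0013). Cytoskeleton and mesenchymal-type genes shifted upwards as well, with 5 of 19 higher (median 0.63, adjusted p = 5.59e-04; adjusted p = 0.27 with an estimated correlation) and 8 higher and 1 lower when adjusted over the list alone. The Notch list did not pass at day 7 (15 members, median -0.30, adjusted p = 0.30), while the Notch ligand gene Jag2, well above background on 1 of 2 control arrays, rose by 3.67 ± 0.34 and Nrarp, a Notch-induced regulator, fell at least 4.91-fold. Proliferation genes shifted upwards (30 members, median 0.23, adjusted p = 0.024; adjusted p = 0.77 with an estimated correlation) with no member called over all genes or when adjusted over the list alone. The list's call ended without control replicate 2 (median 0.18) and without day 7 replicate 1 (median 0.02). It also ended with normexp background correction (camera adjusted p = 0.051) and with no filter on dim probes (0.32).

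Inflammation and antimicrobial genes shifted upwards, with 5 of 16 higher and 1 lower (median 0.92, or 0.91 with dim members at their bounds, adjusted p = 0.0099; adjusted p = 0.27 with an estimated correlation), and 7 higher and 2 lower when adjusted over the list alone. The acute phase gene Saa2 rose at least 18.3-fold and the nitric oxide synthase gene Nos2 9.26-fold. This call was lost when probes had to be well above background on all 7 arrays (median -0.28, adjusted p = 0.88, where its other alternatives went down to 0.0022). Of 24 interferon-stimulated genes 8 rose (median 0.95, adjusted p = 1.87e-10; adjusted p = 0.27 with an estimated correlation) and 15 were higher when adjusted over the list alone, with the chemokine gene Cxcl10 at 2.86 ± 0.33 and the antiviral gene Oas2 at 1.52 ± 0.23. MHC class II genes shifted upwards (7 members, median 2.40, adjusted p = 1.38e-05; adjusted p = 0.31 with an estimated correlation). Of these, Ciita, the class II transactivator, was called (at least 3.07-fold higher), and all 7 were higher when adjusted over the list alone.

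Metabolic genes moved in both directions at day 7. Of 21 xenobiotic metabolism genes 15 fell and none rose (median -2.31, adjusted p = 4.75e-10; adjusted p = 0.31 with an estimated correlation), and 16 were lower when adjusted over the list alone. The glutathione transferase gene Gstm1 was 43.2-fold lower (-5.43 ± 0.37) and the cytochrome gene Cyp2b10 6.89-fold lower (-2.78 ± 0.24). PPAR-alpha target and fatty acid oxidation genes shifted downwards (21 members, 1 higher and 4 lower, median -0.70, adjusted p = 0.0013; adjusted p = 0.31 with an estimated correlation), with 2 higher and 10 lower when adjusted over the list alone. Cyp4a10, a fatty acid hydroxylase gene, fell by 3.52 ± 0.29 and the pantetheinase gene Vnn1 rose by 3.70 ± 0.25. Cholesterol synthesis genes shifted upwards (21 members, 1 higher, median 0.56, adjusted p = 1.07e-04; adjusted p = 0.35 with an estimated correlation), and the called gene Sqle, an epoxidase of sterol synthesis, rose by 1.71 ± 0.26. It was also the 1 member that passed when adjusted over the list alone. Genes of the proximal small intestine fell, with 5 of 14 lower (median -1.15, adjusted p = 0.0019; adjusted p = 0.31 with an estimated correlation) and 1 higher and 8 lower when adjusted over the list alone. The gastrokine gene Gkn3 fell by 2.36 ± 0.25 and the duodenal iron reductase gene Cybrd1, well above background on 1 of 2 day 7 arrays, by 4.60 ± 0.51. Clock genes did not pass as a list (14 members, median -1.02, adjusted p = 0.063), with 2 higher and 5 lower, among them the output genes Dbp (-4.41 ± 0.66) and Ciart (at least 3.98-fold lower). The clock list passed without control replicate 1 (adjusted p = 0.019), without either day 4 replicate or with only the 2 groups compared (0.042) and without day 7 replicate 2 (0.035). It also passed with normexp background correction (0.043), median scaling (0.037), scaling to the probes detected on all arrays (0.047), no filter on dim probes (0.0029) and the replicate block (0.044), within a range from 0.0029 to 0.23 over its alternatives.

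Markers of other cell types were measured beside these groups. Myeloid markers shifted upwards at day 7 (17 members, median 0.24, mean 0.92, adjusted p = 0.0099; adjusted p = 0.27 with an estimated correlation), with 1 called, the neutrophil gene S100a9, which was at least 5.66-fold higher. Fibroblast and stroma markers shifted downwards (7 members, median -0.64, adjusted p = 0.012; adjusted p = 0.27 with an estimated correlation), with Dcn, a matrix proteoglycan gene, at least 3.19-fold lower. When adjusted over the list alone, 5 myeloid markers were higher and 3 fibroblast markers were lower. The fibroblast call ended without day 7 replicate 1 (adjusted p = 0.067) and with normexp background correction (0.070). The myeloid call ended when probes had to be well above background on all 7 arrays (0.37). T cell and intraepithelial lymphocyte markers did not pass (19 members, median 0.00, adjusted p = 0.31), with the cytotoxic granule gene Gzmb higher (1.45 ± 0.25). B cell markers, smooth muscle markers, endothelial markers, pancreas markers and enteric neuron and glia markers did not pass at day 7, with adjusted p of 0.50, 0.58, 0.82, 0.051 and 0.99. The pancreas list, with a median below 0, passed without control replicate 1 (adjusted p = 0.044), with normexp background correction (0.016), with median scaling (0.047), with scaling to the probes detected on all arrays (0.045), with the deposited value table (0.049), with the replicate block (0.050) and with only probes well above background on all 7 arrays (0.029), within a range from 0.016 to 0.32 over its alternatives.

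The count at day 7 was 522 without control replicate 1, 974 without control replicate 2, 807 without day 7 replicate 1, 1067 without either day 4 replicate and 2071 without day 7 replicate 2. Of the 58 called genes named here, 39 were called without each replicate in turn. The other 19 were Mob1b, Ces1d, Lgr5, Sp5, Rnf43, Bmp2, Tac1, Habp2, Ptgs1, Rbp2, Slc2a2, Oas2, Ciita, Sqle, Ciart, Dbp, Gzmb, S100a9 and Dcn, of which 18 lost their call without control replicate 1, 13 without control replicate 2, 15 without day 7 replicate 1 and 4 without each of the other replicates, with adjusted p between 0.051 and 0.15. With normexp background correction the calls of Ciita (0.46, adjusted p = 0.29), Dcn (-0.34, adjusted p = 0.46), Ciart (-1.15, adjusted p = 0.10), S100a9 (1.26, adjusted p = 0.076) and Lgr5 (-1.01, adjusted p = 0.059) ended, the first 4 at sizes below the bounds given. Over all alternatives the adjusted p of these 5 genes was 0.013 to 0.29, 0.018 to 0.46, 0.0055 to 0.10, 0.0090 to 0.076 and 0.018 to 0.14. No filter on dim probes ended those of Lgr5, Sp5, Rnf43, Rbp2, Slc2a2, Gzmb, S100a9 and Dcn (adjusted p between 0.052 and 0.095), and a fit of only the 2 groups those of Lgr5, Rnf43, Slc2a2 and Dcn (0.064 to 0.082). Quantile normalization (0.052) and scaling to the probes detected on all arrays (0.057) also ended that of Rnf43.

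List medians at day 7 also moved. Without day 7 replicate 1 the median was -0.63 for enteroendocrine, 1.57 for MHC class II and 0.35 for cholesterol synthesis genes, the last being 0.23 without control replicate 1. Normexp background correction gave -0.32 for Wnt target, 0.11 for BMP and TGF-beta, 0.19 for Hippo and 0.07 for myeloid genes. With no filter on dim probes it was 0.20 for cytoskeleton, -0.37 for Wnt target and -0.30 for fibroblast genes.

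**Figure D3:**
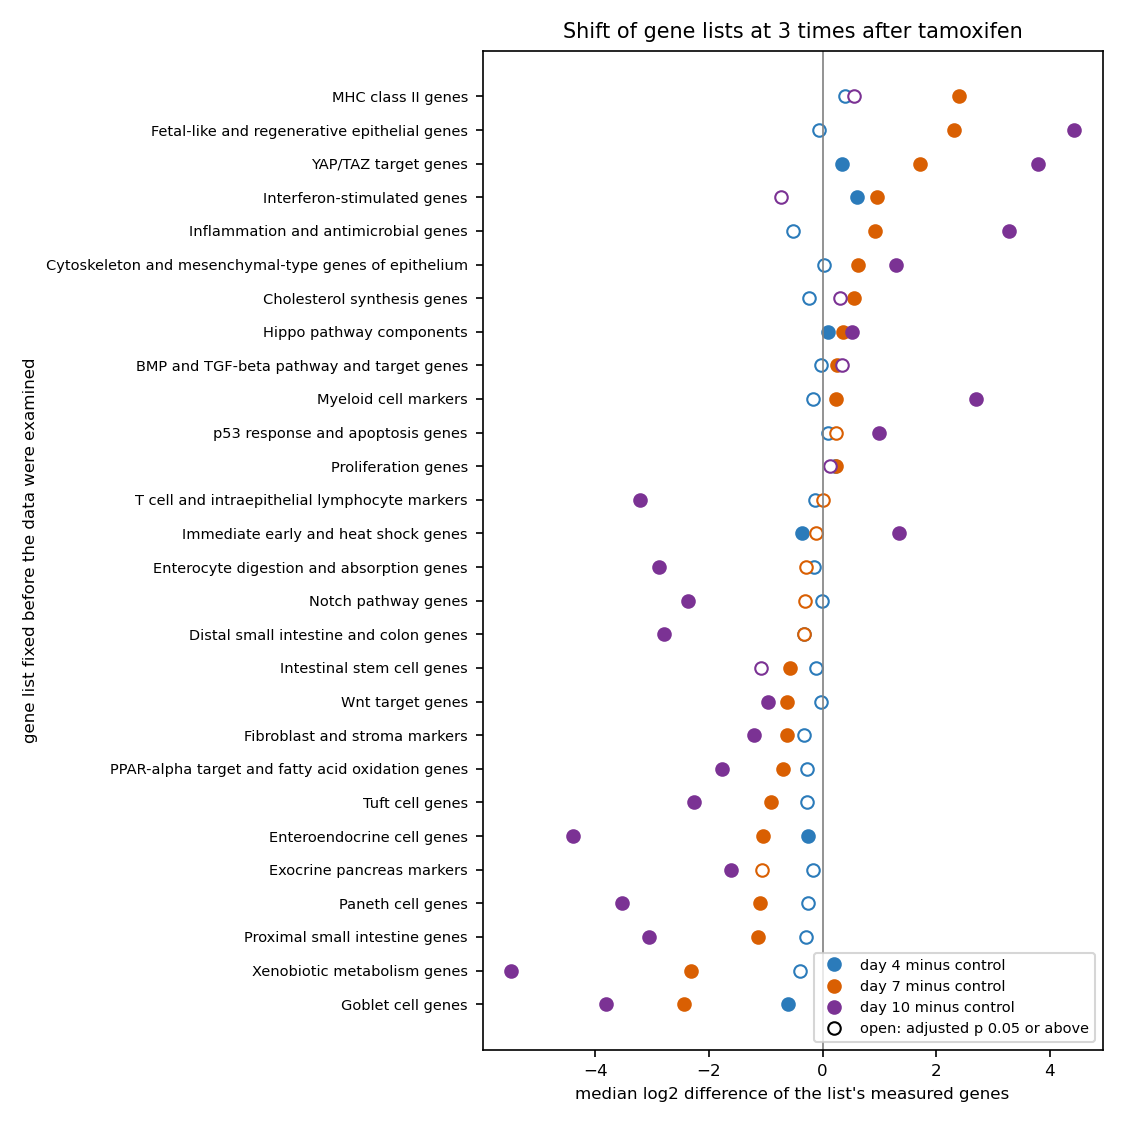
Median log2 difference from control (x axis) of the measured genes of each of 28 lists (y axis) that passed camera at 1 or more of the 3 times, with filled points for an adjusted p under 0.05 and open points for others. Fetal-like genes reached 2.31 at day 7 and 4.43 at day 10, and goblet cell genes went from -0.61 at day 4 to -2.44 at day 7 and -3.82 at day 10.

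The step from day 4 to day 7 was tested directly. Msln was at least 121-fold higher at day 7 than at day 4 (adjusted p = 0.0047), Cst9 at least 91.5-fold, the phospholipase gene Pla2g4c at least 57.0-fold, the phosphate transporter gene Slc34a2 at least 50.5-fold and Efemp1 185-fold, with Efemp1 well above background on 1 of 2 day 4 arrays. Slc16a9 was at least 255-fold lower (adjusted p = 0.0038), Cyp2c55 87.7-fold lower and Cyp2c37 at least 17.3-fold lower by 1 of its probes, the other being not well above background on any array. In total 661 features were called, 307 higher and 354 lower at day 7. Mob1b differed by -0.16 ± 0.22 (adjusted p = 0.77).

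YAP and TAZ target genes rose further from day 4 to day 7 (4 of 18 higher, median 1.20, or 1.11 with dim members at their bounds, adjusted p = 3.80e-08; adjusted p = 0.26 with an estimated correlation), with 9 higher when adjusted over the list alone. Ajuba rose by 2.48 ± 0.28 (adjusted p = 0.017), Ccn1 by 2.01 ± 0.28 (adjusted p = 0.027) and the growth factor gene Areg by 2.23 ± 0.37 (adjusted p = 0.041; 0.053 with median scaling, and between 0.017 and 0.26 over its alternatives). Wnt target genes fell (3 of 18 lower, median -0.41, adjusted p = 0.0050; adjusted p = 0.27 with an estimated correlation), as did stem cell genes (2 of 20 lower, median -0.50, adjusted p = 4.79e-05; adjusted p = 0.26 with an estimated correlation), and 7 members of each were lower when adjusted over the list alone. Ascl2 fell by 1.98 ± 0.28 (adjusted p = 0.028) and Lgr5 by 1.72 ± 0.29 (adjusted p = 0.042). BMP and TGF-beta genes shifted upwards (2 of 24 higher, median 0.34, adjusted p = 0.029; adjusted p = 0.35 with an estimated correlation), with 6 higher and 2 lower when adjusted over the list alone, Bmp8b at 2.50 ± 0.28 and Bmp2 at 1.89 ± 0.33. The Wnt call ended without day 4 replicate 1 (adjusted p = 0.076) and without day 7 replicate 2 (0.11). The BMP and TGF-beta call ended without day 4 replicate 1 (0.13), without day 7 replicate 1 (0.098) or 2 (0.050) and with no filter on dim probes (0.29).

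Goblet cell genes fell further (9 of 16 lower, median -1.99, adjusted p = 3.45e-14; adjusted p = 0.26 with an estimated correlation), with Klk1 at -4.18 ± 0.29 and Agr2 at -2.29 ± 0.21. Fetal-like genes rose (11 of 20 higher, median 2.23, adjusted p = 9.26e-16; adjusted p = 0.26 with an estimated correlation), with Clu at 4.39 ± 0.34. Xenobiotic metabolism genes fell (10 of 21 lower, median -1.88, adjusted p = 2.91e-12; adjusted p = 0.26 with an estimated correlation), with Gstm1 at -4.06 ± 0.37. When adjusted over the list alone, 1 goblet cell gene was higher and 15 were lower, 17 fetal-like genes were higher, and 1 xenobiotic gene was higher and 17 were lower. Nos2 rose by 4.07 ± 0.41 in the inflammation list (6 of 16 higher, 1 lower, adjusted p = 2.54e-04; adjusted p = 0.26 with an estimated correlation), of which 9 were higher and 1 lower when adjusted over the list alone. The inflammation list had a median of 1.14 (1.05 with dim members at their bounds), and its call ended with only probes well above background on all 7 arrays (median 0.18, adjusted p = 0.32). The immediate early gene Egr1 rose by 2.36 ± 0.41 (3 of 19 in its list higher, adjusted p = 0.0013; adjusted p = 0.26 with an estimated correlation), with 6 higher when adjusted over the list alone. That list's call ended with no filter on dim probes (adjusted p = 0.060). The list had shifted downwards at day 4. Against control at day 7 it did not pass under any alternative with the preset correlation, with a median between -0.11 and 0.096. The count of 661 was 39 without day 4 replicate 1, 0 without day 4 replicate 2, 228 without day 7 replicate 1, 1097 without day 7 replicate 2 and 407 without either control replicate, and 2883 features had an unadjusted p under 0.05 where limma called 0. It follows that none of the 21 called genes named for this step was called without each replicate in turn. Of the calls, 46.4% were higher in day 7, a share that was 34.4% of 823 calls with median scaling. It was 67.5% of 228 without day 7 replicate 1 and 37.6% of 1097 without day 7 replicate 2. No filter on dim probes ended the calls of Pla2g4c, Ajuba, Ccn1, Areg, Ascl2, Lgr5, Bmp8b, Bmp2 and Egr1 (adjusted p between 0.053 and 0.11), and normexp background correction that of Pla2g4c (3.79, adjusted p = 0.067, 0.013 to 0.20 over all alternatives). The replicate block ended the limma calls of Lgr5 (adjusted p = 0.057), Areg (0.054) and Egr1 (0.051). A fit of only the 2 groups ended those of Lgr5 (0.075), Areg (0.052), Bmp2 (0.080) and Egr1 (0.076). Median scaling also ended those of Bmp2 (0.057) and Egr1 (0.051), and scaling to the probes detected on all arrays that of Lgr5 (0.054). The median of the YAP and TAZ targets was 0.66 with normexp, 0.68 with no filter and 0.75 with only probes well above background on all 7 arrays. The Wnt target median was -0.20 with normexp and -0.14 with only probes well above background on all 7 arrays. It was -0.16 without day 4 replicate 1 and -0.68 without day 4 replicate 2. The median of stem cell genes was -0.33 with normexp.

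The day 10 group held 1 mouse, so its spread was assumed to be that of the other groups and its differences have no replicate check. The titles number the day 7 samples 1 and 2 and the day 10 sample 1, and the replicate numbers used here follow them. The descriptions instead number the second day 7 sample 3 and the day 10 sample 2. Whether the day 10 mouse came from a larger set is not given in the sources used here. On that array the neutrophil chemokine gene Cxcl5 was at least 4137-fold above control (adjusted p = 6.06e-04), S100a9 at least 3633-fold, the plasminogen activator gene Plat at least 1814-fold, Ccn2 at least 915-fold and Msln, well above background on 1 of 2 control arrays, 8000-fold. Lct, the gene of the brush border enzyme lactase, was at least 7452-fold lower (adjusted p = 1.56e-04), Cyp3a16 at least 1464-fold, Otop3 at least 806-fold, Cyp2c67 at least 609-fold and Cyp3a11 2613-fold lower. In total 6953 features were called, 2586 higher and 4367 lower.

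On the day 10 array 13 of 18 YAP and TAZ target genes were higher and 1 was lower (median 3.79, or 3.41 with dim members at their bounds and 2.27 with only probes well above background on all 7 arrays, adjusted p = 9.56e-08; adjusted p = 0.21 with an estimated correlation), among them the coagulation gene F3 (7.17 ± 0.37). Of 18 Wnt target genes 2 were higher and 8 lower (median -0.95, adjusted p = 0.037; adjusted p = 0.37 with an estimated correlation). Lgr5 was at least 17.6-fold lower and Myc, a growth regulator, was 3.69 ± 0.51 higher. The Wnt call ended with median scaling (adjusted p = 0.059), normexp background correction (0.093), the mean of a gene's probes (0.065) and only probes well above background on all 7 arrays (0.30), within a range from 0.0055 to 0.30 over its alternatives. Stem cell genes did not pass as a list (5 of 20 higher, 10 lower, median -1.09, adjusted p = 0.078), with the transcription factor gene Sox4 3.39 ± 0.29 higher. The list passed with scaling to the probes detected on all arrays (adjusted p = 0.032), with no filter on dim probes (0.012) and without control replicate 1 (0.045), within a range from 0.012 to 0.22. BMP and TGF-beta genes did not pass (7 of 24 higher, 5 lower, median 0.34, adjusted p = 0.10). They passed with normexp background correction (0.024), with no filter on dim probes (0.010) and with only probes well above background on all 7 arrays (0.013). Among them Tgfbr2 was 26.9-fold higher, while Bmp7 was 27.4-fold lower. When adjusted over the list alone, the higher and lower members were 13 and 1 of the YAP and TAZ targets, 3 and 8 of the Wnt targets, 5 and 11 of the stem cell genes, and 8 and 7 of the BMP and TGF-beta genes.

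Epithelial lineage genes were low on the day 10 array. Of 30 enterocyte genes 29 fell (median -2.87, adjusted p = 5.23e-14; adjusted p = 0.21 with an estimated correlation), with the disaccharidase gene Sis 57.4-fold lower. Of 22 enteroendocrine genes 21 fell, of 16 goblet cell genes 15 fell and 1 rose, of 10 Paneth cell genes 8 fell and 1 rose, and of 15 tuft cell genes 8 fell and 1 rose, with adjusted p of 6.00e-13, 2.07e-08, 1.94e-04 and 0.0022, and adjusted p between 0.21 and 0.51 with an estimated correlation. The tuft cell call ended with only probes well above background on all 7 arrays (median -1.16 in place of -2.26, adjusted p = 0.10, where its other alternatives went down to 2.48e-04). Neurog3 was 40.1-fold lower, Klk1 61.9-fold, Defa21 62.5-fold and the tuft cell kinase gene Dclk1 at least 11.6-fold lower. All 20 fetal-like genes were higher (median 4.43, adjusted p = 8.39e-17; adjusted p = 0.16 with an estimated correlation), with Clu 646-fold higher and Anxa1, a regulator of inflammation well above background on 1 of 2 control arrays, 904-fold higher. Of 20 genes of the p53 response and apoptosis 10 were higher and 2 lower (median 0.99, adjusted p = 5.41e-05; adjusted p = 0.21 with an estimated correlation), including the stress cytokine gene Gdf15 (5.59 ± 0.52) and the kinase gene Plk2 (5.45 ± 0.37), well above background on 1 of 2 control arrays. Of 16 inflammation genes 8 were higher and 2 lower (median 3.28, adjusted p = 2.13e-05; adjusted p = 0.16 with an estimated correlation), with Saa2 at least 264-fold higher. The inflammation median was 0.74 with only probes well above background on all 7 arrays (adjusted p = 0.022, the highest of its alternatives, which went down to 1.42e-14) and 5.32 with no filter on dim probes. Adjusted over the list alone, 29 enterocyte, 21 enteroendocrine, 15 goblet cell, 8 Paneth cell and 9 tuft cell genes were lower, and 20 fetal-like, 11 p53 response and 9 inflammation genes were higher.

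Markers of other cells moved apart on the day 10 array. Of 19 T cell and intraepithelial lymphocyte markers 18 fell (median -3.22, or -3.12 with dim members at their bounds, adjusted p = 1.57e-09; adjusted p = 0.21 with an estimated correlation), including the T cell receptor component gene Cd3g (-4.85 ± 0.29) and the granzyme gene Gzma (-4.50 ± 0.28). Of 17 myeloid markers 12 rose (median 2.70, adjusted p = 9.20e-08; adjusted p = 0.16 with an estimated correlation), including the complement gene C1qa of macrophages (2.84 ± 0.27). Adjusted over the list alone, 18 T cell markers were lower and 13 myeloid markers higher. Fibroblast markers shifted downwards (median -1.20, adjusted p = 0.030; adjusted p = 0.21 with an estimated correlation), with 5 of 7 lower when adjusted over the list alone and a median of -0.74 with normexp background correction and -0.68 with no filter on dim probes. Exocrine pancreas markers also shifted downwards, with 5 of 7 lower over all genes and over the list alone (median -1.61, adjusted p = 0.012; adjusted p = 0.21 with an estimated correlation). That call ended with no filter on dim probes (adjusted p = 0.17, where its other alternatives went down to 0.0075). B cell, smooth muscle, endothelial, and enteric neuron and glia markers did not pass, with adjusted p of 0.90, 0.42, 0.79 and 0.75. The median difference of all features was -0.15 in the main scaling, and it moved by 0.23 with scaling to the probes detected on all arrays and by -0.20 with median scaling. The share of calls that were higher was 37.2% in the main scaling, 49.1% and 27.6% with these alternatives, and the count was 4578 without control replicate 1.

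The calls at day 4 and day 7 were compared as sets. All 8 genes called at day 4 were also called higher at day 7, where 0.24 would be shared by independent lists of these sizes and 0.06 on average in 50 simulations of unchanged groups against shared controls (highest 1). No group was changed in the simulations, so few features were called and a low shared count followed by construction. They do not show how much overlap shared controls add to sets of calls as large as those observed. Across features the differences at day 4 and day 7 had a correlation of 0.54 (0.50 in the simulations) and a covariance of 0.24 (0.066 in the simulations); features are not independent replicates. Day 7 and day 10 shared 1343 calls in the same direction and 73 in opposite directions, where independent lists would share 76.4 higher and 197 lower calls. The correlation was 0.61 (0.41 in the simulations) and the covariance 0.95 (0.066 in the simulations). With 2 control arrays the controls could not be split into parts of at least 2, and part of each excess can come from the shared controls. The overlap of day 4 and day 7 calls was between 1 and 6 genes when 1 replicate was left out.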

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

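The tests of explanations and the test of day 10 minus day 7 were chosen after the result was seen, while the test of day 7 minus day 4 was planned.

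Levels differed between the day 4 and day 7 knockout arrays for 51 named genes by limma's test of day 7 minus day 4. That test compares knockout arrays alone and has no control for each day. Slide row and hour of collection therefore cannot be told apart from the time after deletion. Among genes higher at day 7, the log2 differences were 7.53 for Efemp1, 4.85 for Ccn2, 4.39 for Clu, 4.17 for Sh3tc2, 4.07 for Nos2, 3.82 for Gm10046, 3.71 for Saa2, 3.38 for Pla1a, 2.50 for Bmp8b, 2.48 for Ajuba, 2.41 for Vnn1, 2.36 for Egr1, 2.25 for Mgat4c, 2.24 for Cxcl10, 2.23 for Areg, 2.09 for Ptgs1, 2.03 for Tdrp, 2.01 for Ccn1, 1.89 for Bmp2, 1.73 for Tead1 and 1.72 for Sqle. Among genes lower at day 7 they were -1.61 for Tac1, -1.72 for Lgr5, -1.84 for Defa21, -1.98 for Ascl2, -2.06 for Cyp2b10, -2.29 for Agr2, -2.41 for Cyp4a10, -2.78 for Neurog3, -4.06 for Gstm1, -4.13 for Dbp, -4.16 for Klk1b26, -4.17 for Klk1b4, -4.18 for Klk1, -4.26 for Cybrd1, -4.70 for Cyp3a57, -5.02 for Ces1d, -5.08 for Ces1f, -5.25 for Otop3 and -6.46 for Cyp2c55. Of these, Efemp1, Ccn2 and Saa2 were well above background on 1 of 2 day 4 arrays, and Cybrd1, Ces1d and Cyp2c55 on 1 of 2 day 7 arrays. The other genes were not well above background on either array of 1 of the days, so that the data give a bound and the fitted difference is no measured size. Msln was at least 121-fold higher (fitted difference 8.86), Cst9 at least 91.5-fold (8.67), Pla2g4c at least 57.0-fold (7.71), Slc34a2 at least 50.5-fold (6.50), S100a9 at least 5.44-fold (4.26) and Ciita at least 3.34-fold (1.90). Slc16a9 was at least 255-fold lower (-9.40), Cyp2c37 at least 17.3-fold (-6.03), Ciart at least 4.21-fold (-4.10), Dcn at least 4.12-fold (-2.36) and Nrarp at least 2.81-fold (-1.49). Without day 4 replicate 2 no feature was called in this comparison, while 2883 had an unadjusted p under 0.05.

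The same difference between days passed camera for 24 lists. The median log2 difference was 1.20 for YAP and TAZ targets, 2.23 for fetal-like genes, 2.01 for MHC class II, 1.14 for inflammation, 0.784 for cholesterol synthesis, 0.499 for immediate early and heat shock, 0.453 for interferon-stimulated, 0.409 for myeloid, 0.374 for cytoskeleton, 0.336 for BMP and TGF-beta, 0.276 for Hippo and 0.261 for T cell genes. It was -1.99 for goblet cell, -1.88 for xenobiotic, -1.10 for clock, -1.07 for Paneth cell, -0.821 for enteroendocrine, -0.663 for proximal intestine, -0.566 for tuft cell, -0.501 for stem cell, -0.427 for PPAR-alpha, -0.414 for Wnt target, -0.395 for Notch and -0.387 for fibroblast genes. With an estimated correlation none of these passed, the lowest adjusted p being 0.26. The calls of YAP and TAZ target, stem cell, Paneth cell, goblet cell, enteroendocrine, fetal-like, MHC class II, cholesterol, PPAR-alpha, xenobiotic and proximal intestine genes stayed under every alternative with the preset correlation. Leaving out 1 replicate ended the call of T cell markers (adjusted p = 0.102 without day 4 replicate 2, 0.234 without day 7 replicate 2 and 0.0551 without either control replicate). It ended that of tuft cell genes (0.271 without day 4 replicate 2, and 0.522 without day 7 replicate 1, where the median was -0.194). The Hippo call ended without day 7 replicate 1 or 2 (0.111 and 0.0503) and the Notch call without day 7 replicate 1 (0.0711). The fibroblast call ended without day 4 replicate 1 (0.077) and without day 7 replicate 1 (0.123). Leaving out 1 replicate also ended the calls of Wnt target genes (0.0759 without day 4 replicate 1 and 0.112 without day 7 replicate 2) and BMP and TGF-beta genes (0.132 without day 4 replicate 1, 0.0979 without day 7 replicate 1 and 0.0503 without day 7 replicate 2). With no filter on dim probes the calls of Hippo (0.435), T cell (0.526), BMP and TGF-beta (0.289), interferon-stimulated (0.179), cytoskeleton (0.0642), fibroblast (0.0642) and immediate early genes (0.0598) ended. With only probes well above background on all 7 arrays those of inflammation (0.32), Hippo (0.132), myeloid (0.0763), T cell (0.0737), tuft cell (0.0734) and clock genes (0.0545) ended. Normexp background correction ended the calls of fibroblast (0.125) and Notch genes (0.0713), and the mean of a gene's probes that of Hippo genes (0.159). The replicate block (0.0505) and a fit of only the 2 groups (0.0551) ended that of T cell markers.

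From day 7 to day 10 the granzyme gene Gzmb differed by -6.25 after a rise at day 7. It was picked for opposite calls at these days against the same controls. That the test of day 10 minus day 7 passed for it follows largely from this choice. Probes of the genes S100a8, Anxa8, Cxcl1 and Saa3 lay outside the features tested because they were well above background on the day 10 array alone, where they were at least 1280-fold, 576-fold, 262-fold and 133-fold above control. They were chosen after their values were seen.

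The signal of 1 Esr1 probe was present on all 5 knockout arrays and absent above background in controls. Its SD over the knockout arrays was 0.282 on the log2 scale, and its means at the 3 times lay within 0.612. The other 2 Esr1 probes differed from control by at most 0.29 over the knockout arrays and were not well above background on any array. No array showed that these 2 probes can detect an Esr1 transcript. Their lack of signal therefore cannot decide on a full-length endogenous transcript. A candidate explanation is hybridization of the CreERT2 transgene transcript, which contains part of an oestrogen receptor sequence and is carried by knockout mice only. Which part of Esr1 the probe covers was not examined.

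The day 10 array differed from all others, with 6953 calls from 1 mouse. Of these calls, 93.6% stayed called in the same direction with quantile normalization and 86.7% with scaling to the probes detected on all arrays, which argues against scaling as the whole cause, although the share of higher calls moved from 37.2% to 49.1% with the latter. T cell and intraepithelial lymphocyte markers fell (median -3.22) while myeloid markers rose (2.70). S100a9 among the myeloid markers is also in the inflammation list. A rise of every other cell type would raise both marker lists, but intraepithelial lymphocytes lie in the epithelium and could be lost with it. The fall of their markers therefore cannot decide on a loss of epithelium. A gain of myeloid cells alone would lower enterocyte genes alike, whereas their differences had a robust SD of 1.46 against a median SE of 0.338, which argues against it as the whole cause. A loss of epithelium, a part from myeloid cells, the condition of this mouse and time after deletion stay open. They cannot be told apart with 1 array, where the day 7 and day 10 differences correlated at 0.613 over features and shared controls alone gave 0.41.

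Clock output genes were low at day 7, with a median difference of -2.15 over Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2 and Ciart, although Per3 and Ciart were not well above background at day 7, so that their fitted differences are no measured sizes. Genes of the opposite phase (Arntl, Npas2, Clock, Cry1 and Nfil3) had a median of 0.917, which is consistent with collection at another time of day. The opposite-phase median is the value of Arntl (0.92 ± 0.29), which did not pass the test. Nr1d1 (-0.15 ± 0.39), Nr1d2 (-0.85 ± 0.30) and Clock (0.11 ± 0.22) did not pass either. Cry1 also did not pass and was not well above background at day 7. A direct effect of Mob1a and Mob1b deletion on the clock cannot be told apart from collection at another time of day, because hours of collection are not given in the sources used here. Most of these genes were chosen after their values were seen, and other measured members of the clock list were left out. On the day 10 array the fitted differences from control went the same way for most of them (Dbp -6.3, Tef -2.6, Npas2 1.45, Nfil3 1.70). Clock went the other way (-0.28).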

How the results depend on the processing

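Scaling to the probes detected on all arrays was chosen after the data were seen, and the other alternatives were planned; where no reason is given, the cause was not tested. The 8 calls at day 4 became 17 with normexp, 27 with median scaling, 4 with detected-probe scaling, 2 with no filter on dim probes, 24 with only probes well above background on all 7 arrays, 36 with an intensity trend and 3 with only the 2 groups compared, and the overlap with day 7 calls (8) became 14, 26, 4, 2, 23, 35 and 2. The 1847 calls at day 7 became 913 with no filter and 1067 with only the 2 groups compared, and the 661 of day 7 minus day 4 became 116 and 407. Without the filter 48984 features were tested, and the median of all features moved by 0.18 at day 7 and 0.27 for day 7 minus day 4. With only 2 groups fewer arrays estimate the spread. Leaving out the day 10 array gave equal counts by construction, since a lone array adds nothing to the spread. With 1 replicate left out, the counts ranged from 1 to 8 at day 4, 522 to 2071 at day 7, 0 to 1097 for day 7 minus day 4 (0 by limma without day 4 replicate 2, with 2883 at an unadjusted p under 0.05) and 4578 to 7481 at day 10, and the overlap from 1 to 6. A group left with 1 array was assumed to vary like the others.

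The replicate block gave 2 calls at day 4, an overlap of 2, and 1866, 720 and 6481 calls for day 7, day 7 minus day 4 and day 10. Deviations of arrays with the same number correlated at 0.0083 (control and day 4), 0.086 (control and day 7) and 0.25 (day 4 and day 7). Each value compares a single difference per group, so these values cannot exclude that arrays of the same number share a condition. The numbers were not treated as pairs because the replicates were different mice per the design text. A block for slide or scan was not run because there was 1 of each.

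With an estimated correlation the adjusted p for YAP and TAZ targets was 0.662 at day 4, 0.268 at day 7, 0.256 for day 7 minus day 4 and 0.209 at day 10. For day 7, day 7 minus day 4 and day 10 it was 0.355, 0.268 and 0.366 for Wnt targets, and for day 7 and day 7 minus day 4 it was 0.309 and 0.256 for stem cell genes and 0.348 and 0.351 for BMP and TGF-beta genes. In simulated data this test called a shifted list in 0 of 20 runs, so its misses do not show the lists unmoved. The simulated genes varied independently, so the preset correlation was not tested there on members that vary together. The Wnt call at day 7 ended with normexp (0.0514), the mean of a gene's probes (0.0522) and only 2 groups (0.0522), and at day 10 with normexp (0.0926), median scaling (0.0587), all 7 arrays above background (0.298) and the mean of probes (0.0649). The BMP and TGF-beta call ended with no filter at day 7 (0.411) and for day 7 minus day 4 (0.289), and at day 10 the list passed with normexp (0.0241), no filter (0.010) and all 7 arrays above background (0.0133). Stem cell genes passed at day 10 with detected-probe scaling (0.0319) and no filter (0.0124).

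With 1 replicate left out, the adjusted p at day 4 ranged from 1.86e-08 to 0.0013 for YAP and TAZ, 0.176 to 0.842 for Wnt, 0.233 to 0.946 for stem cell and 0.216 to 0.856 for BMP and TGF-beta genes. At day 7 the ranges were 7.04e-11 to 7.21e-09, 0.00586 to 0.216, 3.94e-04 to 0.0134 and 0.0141 to 0.0629, for day 7 minus day 4 6.00e-10 to 1.52e-06, 2.99e-04 to 0.112, 2.13e-06 to 0.00419 and 0.00869 to 0.132, and at day 10 1.39e-08 to 2.92e-07, 0.0266 to 0.0427, 0.0450 to 0.102 and 0.0891 to 0.132. Proliferation genes changed direction at day 4 without day 4 replicate 1 (adjusted p = 0.216, within a range from 1.63e-12 to 0.216) and for day 7 minus day 4 without day 4 replicate 2 (0.00457, within a range from 3.37e-04 to 0.643). Signal over background limits dim genes, whose folds are bounds.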

Other observations

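The gene groups of this part were planned, while the test of day 10 minus day 7 was chosen after the result was seen.

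On the day 10 array 17 of 21 xenobiotic metabolism genes were lower and 1 was higher (median -5.49, camera adjusted p = 2.58e-09; adjusted p = 0.23 with an estimated correlation). Genes of the proximal small intestine were lower in 10 of 14 cases (median -3.05, adjusted p = 1.29e-05; adjusted p = 0.21 with an estimated correlation) and those of the distal intestine and colon in 12 of 17, with 1 higher (median -2.79, adjusted p = 3.01e-05; adjusted p = 0.21 with an estimated correlation). Notch pathway genes were lower in 9 of 15 cases and higher in 2 (median -2.38, adjusted p = 0.0084; adjusted p = 0.21 with an estimated correlation), and PPAR-alpha and fatty acid oxidation genes lower in 13 of 21 and higher in 3 (median -1.77, adjusted p = 0.012; adjusted p = 0.37 with an estimated correlation). Cytoskeleton and mesenchymal-type genes were higher in 11 of 19 cases (median 1.29, adjusted p = 9.08e-08; adjusted p = 0.16 with an estimated correlation) and immediate early and heat shock genes in 8 of 19, with 1 lower (median 1.35, adjusted p = 5.64e-05; adjusted p = 0.21 with an estimated correlation). When adjusted over the list alone, the higher and lower members were 1 and 18 of the xenobiotic, 0 and 11 of the proximal, 1 and 12 of the distal, 2 and 10 of the Notch, 3 and 15 of the PPAR-alpha, 13 and 0 of the cytoskeleton and 9 and 1 of the immediate early genes. With members that were not well above background in 1 group at their bounds, the median was -5.40 for the xenobiotic, -2.63 for the distal and -1.56 for the Notch genes. With normexp background correction it was -1.84 for the distal and -0.99 for the Notch genes.

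Interferon-stimulated genes rose at day 7 (8 of 24), while on the day 10 array 11 were lower and 1 was higher and the list did not pass (median -0.74, adjusted p = 0.11, and 0.027 with no filter on dim probes); the difference between these days was not tested for the list. Isg15, an antiviral ubiquitin-like gene chosen after its values were seen, differed from control by 1.20 at day 7 and -1.46 at day 10. The gasdermin gene Gsdmc4 differed by 4.82 and then -3.55, and was also chosen after its values were seen. Both were picked among features called in opposite directions at these days against the same controls. That the test of day 10 minus day 7 passed for both follows largely from this choice and is no separate support. In all, 73 features were called in opposite directions at day 7 and day 10. MHC class II genes, which shifted upwards at day 7, had a median of 0.56 at day 10 with none called over all genes by limma (adjusted p = 0.48 by camera), where 10045 features had an unadjusted p under 0.05. The day 10 array had 2054 probes well above background on it alone, against 205 to 596 for each other array.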
